A study of Mus musculus with 7 samples.

How the data were processed

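Lymph node RNA of mice was hybridised to 7 dual-dye Agilent arrays, with PLN RNA in the red (Cy5) and MLN or ILN RNA in the green (Cy3) channel on every array, per the labels. No array had the dyes swapped. Each channel held a pool of 5 mice of BALB/c, FVB, NOD or NOD.B10, 12 weeks old, per the labels. For the NOD.B10 arrays the title and source name give NOD.B10 and the strain entry gives NOD, and the title and source name were used.

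Scanner output of Agilent Feature Extraction 8.5.1.1 was used, whose spot and background means are intensity values in linear units, per the file headers. Its LogRatio is the log10 of red over green after spatial detrending, linear and lowess dye normalization and replacement of dim signals by surrogates, per the file headers. Marks for saturated, outlier and well-above-background spots are 0 or 1 in the deposited files. The value table deposited for the whole series holds log2 values, which by comparison with the scanner values are the log2 of red over green with 0.0018 to 0.0798 subtracted per array, at correlations of 1 on 6 arrays and 0.999979 on 1. On the FVB array of the MLN values departed from this by up to 0.96, and on the other arrays by at most 5.1e-05. The column medians of the deposited table were 0.0073 to 0.0935, and why these constants were chosen is not given in the sources used here. All its columns were assigned to arrays by name.

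Background was corrected with normexp (offset 50) and each array normalized by loess with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with control and outlier spots at weight 0 and outlier spots then left out. Spots of a probe were averaged. Of 41174 probes, 22207 were named through RefSeq accessions in a gene table of assembly GRCm38.p6, used for names only, and 2131 through the symbol in the files' descriptions, while 16836 had no symbol and kept their probe name, which gave 17634 symbols. No coordinates were used. A probe was kept where it was well above background in either channel on at least 3 of the 7 arrays (35817 probes, 87.0%), and the probe with the highest mean signal over the arrays stood for a gene, which gave 29757 genes and unnamed probes, 16184 with a symbol. 29756 could be tested.

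A linear model in limma with a coefficient for PLN over MLN (4 arrays) and another for PLN over ILN (3 arrays) was fitted to all 7 arrays, which share an estimate of the spread with 5 residual and 3.85 prior degrees of freedom. ILN over MLN is the difference of both coefficients. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over genes, and genes with an adjusted p under 0.05 were called. A gene-specific dye effect remains in both PLN comparisons. Levels per channel are log2 values after loess and Aquantile scaling and are open to dye bias. Where a probe was well above background on no array of a group (Hoxc9 in PLN), a ratio is given as a lower bound, the mean of the bright group over the higher of the dim probe's level and the lowest level well above background. Ratios of genes that were well above background on some arrays of a group only (H2-Ea, Ins2 and Pdgfrl in PLN over ILN, Il1rl1 and Csn3) are given as measured.

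The comparisons, the tests, most alternatives, 36 gene lists and the rule for named genes were fixed before the data were examined. The lists were pancreatic acinar, pancreatic islet, duct epithelium, intestinal epithelium, white adipose, brown adipose, mammary and skin epithelium, skeletal muscle, smooth muscle and pericyte, fibroblastic stroma, lymphatic endothelium, blood endothelium, peripheral node addressin synthesis, retinoic acid and gut homing, posterior Hox and hindlimb, anterior Hox and splanchnic, mesothelium, neural and glial, B cell, plasma cell, germinal centre, T cell, regulatory and activated T cell, cytotoxic and NK, type 17 and innate lymphoid, type 2 immunity, dendritic cell, macrophage and monocyte, neutrophil, mast cell, type I interferon response, interferon gamma response, cell cycle, immediate early and stress, erythroid and circadian clock. Each was tested with camera (preset correlation 0.01, and an estimated correlation as an alternative) in each comparison on 29351 genes measured on all arrays, with adjustment over all 108 tests. With the preset correlation 27 of these tests passed (9, 6 and 12 in PLN over MLN, PLN over ILN and ILN over MLN), and with an estimated correlation 0. In 18 list results, 0 of them past the threshold, the median, the mean and the test differed in sign.

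Named genes were, per comparison, the 10 largest called genes in each direction with a symbol (no clone, RIKEN or predicted names) and the same sign on every array (for ILN over MLN, no overlap of the groups of arrays). Up to 3 called members of each list with the largest ratios were added, or the member with the largest ratio where a passing list had none. Aire, Deaf1, Ins2, Madcam1, Nkx2-3, Aldh1a2, Cyp26b1, Glycam1 and H2-Ea were named in every comparison, and up to 6 genes in each direction for NOD against NOD.B10. Other list members given as examples (Irf7, Cd6, Tbx1, Cnn1 and others) and the genes named under a left-out array were chosen after their values were seen. Results of 4 of the named genes are not reported here, though they stay in the counts of called and named genes and were left out of the checks for outlying arrays and strains.

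The headers place the BALB/c and NOD arrays of the MLN on an earlier scanner and the other 5 arrays on a later one, where the NOD.B10 array of the ILN had a session of its own, and median net spike-in signals were 36.5 to 64.1 on the earlier scanner and 24416 to 65212 on the later one. Each array lay on its own slide, so slide could not be a block. Scanner was used as a block, and the later scanner alone, as alternatives added after the data were seen. Arrays of the same strain were checked for shared deviations from the mean of their comparison, which over genes correlated at r = 0.146 (FVB), 0.080 (NOD) and 0.115 (NOD.B10). Pairs of different strains correlated at -0.274 to 0.233, a range that holds the pairs of a strain but cannot exclude a weak pairing. The consensus correlation within strain was 0.132. Strain, the source of this pairing in the labels, was also fitted as a block. Other alternatives were other background corrections, normalizations, filters, probe rules, moderation, array weights, averaging of NOD and NOD.B10 and leaving out each array. The pipeline was tested on simulated data of 29757 genes with 100 genes changed at each size. At a log2 change of 1 it recovered 98 in PLN over MLN, 98 in PLN over ILN and 96 in ILN over MLN, at a change of 2 it recovered 100 in each, with 14, 13 and 15 false calls. The simulated errors were independent between arrays, with spreads drawn from all genes, and each change was the same on every array. Recovery of genes whose ratios vary widely between arrays, such as acinar genes, was not simulated. Of 33 acinar genes 30 had a log2 ratio of at least 1 in PLN over MLN, and 0 were called. Tables were summarised and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.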

Results

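The arrays measured RNA of lymph nodes from 12-week-old female mice, each sample being pooled tissue of 5 mice of a single strain. On all 7 dual-dye Agilent arrays the pancreatic lymph node (PLN), which drains the pancreas, carried the red dye Cy5. The green dye Cy3 marked the mesenteric lymph node (MLN), which drains the gut, on 4 arrays (BALB/c, FVB, NOD and NOD.B10). It marked the inguinal lymph node (ILN), which drains skin and the mammary fat pad, on 3 arrays (FVB, NOD and NOD.B10). NOD mice develop autoimmune diabetes, and NOD.B10 mice differ from them at the major histocompatibility complex (MHC). The median spot signal was 68.0 to 105 intensity units in the PLN channel and 86.1 to 199 in the channel of the other node. Between 46.0% and 59.1% of probes were well above background in the PLN channel, and between 50.8% and 88.9% in the other channel. Over genes, which are not independent replicates, the log2 ratios of the BALB/c array correlated with those of the other arrays at r = 0.0779 to 0.344. The other arrays correlated with each other at r = 0.404 to 0.689. Each strain gave 1 pool per array and node, so p-values measure the spread between the pools of different strains. The number of arrays limits the precision.

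PLN and MLN were compared to find the genes that a node draining the pancreas expresses at another level than a node draining the gut. Genes of the acinar cells of the pancreas, which secrete digestive enzymes, had a median log2 ratio of 3.01 in PLN over MLN, above 0 on 4 of 4 arrays. The list passed the gene list test (adjusted p = 3.1e-25), but not with an estimated correlation (adjusted p = 0.458 with an estimated correlation). Of the 33 measured, 32 were higher in PLN when adjusted over the list alone, and 0 passed over all genes tested. Reg1, a secreted protein of acinar cells, measured 4.11 ± 3.13 (SD, n = 4), a 17.2-fold ratio with an adjusted p of 0.167, and its PLN spot was saturated on 1 array. The BALB/c array had an acinar median of 0.12, and its highest acinar member was at 0.49. On that array the median log2 level of the acinar genes was 13.5 in PLN and 13.1 in MLN. In the MLN and ILN channels of the other arrays it was 9.05 to 11.3. Ins2, which encodes insulin, measured 2.01 ± 1.19 (SD, n = 4; adjusted p = 0.167) and was above 0 on 4 of 4 arrays. Islet genes had a list median of 0.07, which was -0.05 with median centring of each array in place of loess, 0.28 with offset 0, 0.44 with Agilent's LogRatio and 0.41 in the deposited values (adjusted p = 0.0196; adjusted p = 0.579 with an estimated correlation). Of the 21 measured, 3 were higher adjusted over the list alone.

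Genes induced by type I interferon, an antiviral cytokine, had a median log2 ratio of -0.29 in PLN over MLN on the loess scale and of 0.16, the opposite sign, with median centring. The median on the loess scale was below 0 on 4 of 4 arrays (adjusted p = 6.45e-09; adjusted p = 0.485 with an estimated correlation). It was -0.64 on the NOD and -0.46 on the NOD.B10 array, and -0.11 and -0.07 on the BALB/c and FVB arrays. With offset 0, Agilent's LogRatio and the deposited values the list median of the comparison was -0.44, -0.53 and -0.56. Of 25 measured, 12 were lower adjusted over the list alone and 0 passed over all genes tested. Rtp4 was at -0.92 ± 0.65 and Isg15, a ubiquitin-like antiviral protein, at -0.73 ± 0.83 (SD, n = 4). On the NOD array the log2 level of Isg15 was 7.99 in PLN and 9.86 in MLN, and on the BALB/c array 8.84 in both. Irf7, a transcription factor of the interferon response, was at -0.42. Genes of the interferon gamma response had a median of -0.13, which was 0.75 with median centring (adjusted p = 0.00898; adjusted p = 0.485 with an estimated correlation). In the same 3 settings it was -0.23, -0.24 and -0.27. Of 15 measured, 2 were lower adjusted over the list alone. Iigp1, an interferon-induced GTPase, measured -0.40 ± 0.14 (SD, n = 4) and turned above 0 with median centring.

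Erythroid genes, which mark red blood cells, had a median of 0.94 in PLN over MLN, above 0 on 4 of 4 arrays (adjusted p = 0.00083; adjusted p = 0.485 with an estimated correlation). The median was 1.42 with offset 0, 1.72 with Agilent's LogRatio and 1.68 in the deposited values. Adjusted over the list alone, 5 of 6 were higher. Hba-a1, a chain of haemoglobin, measured 2.24 ± 1.21 (SD, n = 4). The erythroid median was 2.23 on the BALB/c array and 0.32 to 0.65 on the others. The genes that build peripheral node addressin, a ligand on high endothelial venules, had a median of 0.12 (adjusted p = 0.00632; adjusted p = 0.458 with an estimated correlation). Adjusted over the list alone, 3 of 7 were higher, among them Glycam1 at 0.62 ± 0.28 and Fut7 at 0.48 ± 0.13 (SD, n = 4). Neutrophil genes had a median of 0.12, and 0 of 13 passed adjusted over the list alone (list adjusted p = 0.00569; adjusted p = 0.577 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, was at 1.35 ± 1.01 (SD, n = 4), and at 0.87 without the BALB/c array, where it was 2.82. The neutrophil median was 0.37 with offset 0, 0.66 with Agilent's LogRatio and 0.69 in the deposited values. The median of the genes of type 2 immunity was 0.18, and 0 of 11 passed adjusted over the list alone (list adjusted p = 0.0265; adjusted p = 0.382 with an estimated correlation). Il1rl1, the receptor of interleukin 33, measured 0.55 ± 0.58 (SD, n = 4), with 1 of its 2 probes of the opposite sign. With median centring the addressin and type 2 medians were 0.36 and 0.53, with offset 0 they were 0.23 and 0.34, with Agilent's LogRatio 0.32 and 0.29 and in the deposited values 0.29 and 0.26.

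Posterior Hox genes, which pattern the hind body, had a median of -0.06 in PLN over MLN, and -0.19 with median centring (adjusted p = 0.0245; adjusted p = 0.382 with an estimated correlation). The median was -0.19 with offset 0, -0.28 with Agilent's LogRatio and -0.26 in the deposited values. Of the 10 measured, Hoxc9 was lower adjusted over the list alone. It was not well above background in any PLN sample and was at least 1.42-fold lower in PLN than in MLN (adjusted p = 0.131). Within the later scanner its measured difference was smaller (adjusted p = 0.493). Aldh1a2, an enzyme of retinoic acid synthesis, was at -0.66 ± 0.11 (SD, n = 4; adjusted p = 0.117), with the sign turned by median centring. Nkx2-3, a transcription factor of gut-associated vessels, was at -0.23 (adjusted p = 0.358), also turned by median centring. Madcam1, the vascular addressin of mucosal tissue, was at 0.21 (adjusted p = 0.602). Cyp26b1, which degrades retinoic acid, was at 0.02 (adjusted p = 0.904) on the loess scale and -0.07 on the Agilent scale.

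limma called 0 of 29756 genes between PLN and MLN at an adjusted p under 0.05, with a lowest adjusted p of 0.0820. An unadjusted p under 0.05 was reached by 4622 genes (1488 by chance). Without the BALB/c array 46 genes were called, 24 of them acinar genes, and without the FVB array of the ILN 9 were called. The count was 37 with no background correction, 10 with a stricter filter of probes and 189 with array weights. Within the later of 2 scanners 19 were called, 9 of them acinar genes, against 0 with scanner as a block. Within that scanner and with scanner as a block, the acinar medians were 3.50 and 3.55, the type I interferon medians -0.27 and -0.27, and the addressin medians 0.20 and 0.20. The block absorbs the MLN arrays of the earlier scanner, so both settings estimate the same ratio and differ only in its spread. The erythroid medians were 0.60 and 0.60 (adjusted p = 0.00367 and 0.0818). Lost in both were the islet (medians 0.02 and -0.0001), neutrophil (0.11 and 0.11), type 2 (0.17 and 0.17), posterior Hox (-0.09 and -0.09) and interferon gamma lists (-0.07 and -0.07). Islet genes also lost their call without the BALB/c (adjusted p = 0.0814), FVB (0.0814) or NOD array (0.107). Neutrophil genes lost it without BALB/c (0.148) and interferon gamma genes without NOD (0.135).

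**Figure D1:**
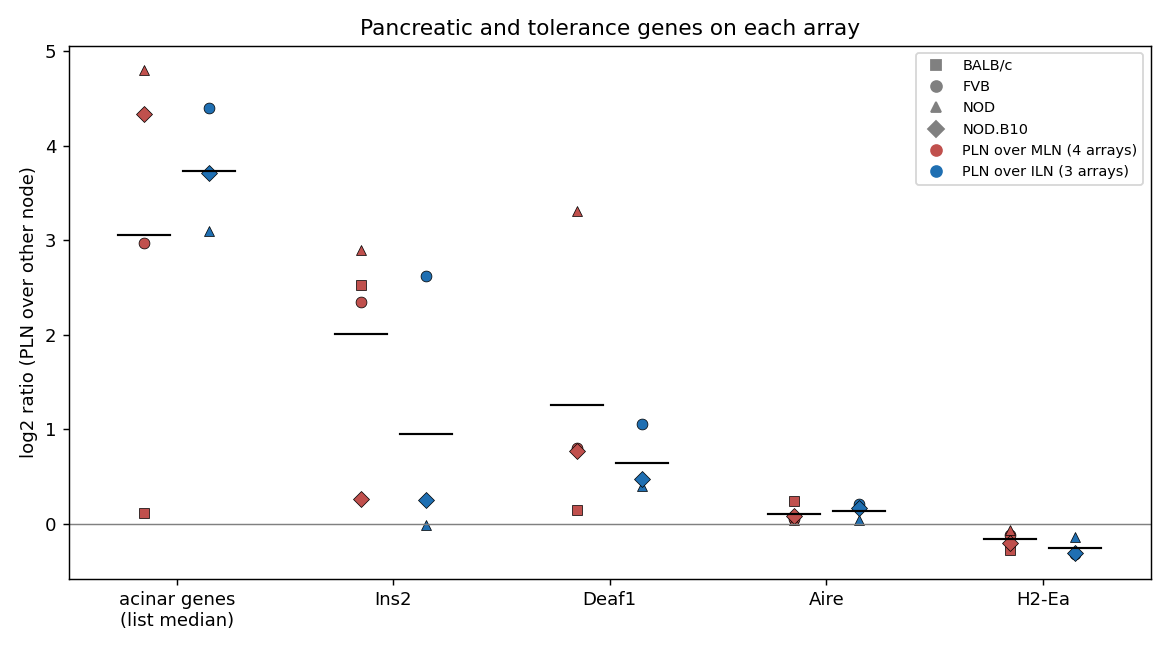
Log2 ratio of PLN over the other node (vertical axis) on each array for the median of the acinar gene list and for the genes Ins2, Deaf1, Aire and H2-Ea, with points coloured by the other node, shaped by strain, and bars at the mean of each comparison. The acinar median is 0.12 on the BALB/c array and 2.98 to 4.80 on the others, and the H2-Ea ratios against MLN, below 0 here, turn sign on average with median centring of each array and in the deposited values.

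PLN and ILN were compared to set the pancreatic node against a node that drains skin and fat. limma called 589 genes, 450 higher and 139 lower in PLN, of which 48 and 6 changed at least 2-fold. Acinar genes rose in PLN (list median 3.53, above 0 on 3 of 3 arrays, adjusted p = 1.29e-21; adjusted p = 0.458 with an estimated correlation). Over all genes tested 15 of 33 rose and 18 did not pass, and adjusted over the list alone 32 were higher. The carboxypeptidase gene Cpb1 rose 32.1-fold (log2 5.00 ± 0.97, SE of the fit, n = 3; adjusted p = 0.0408) and the lipase gene Cel 20.8-fold (4.38 ± 0.75). The amylase gene Amy2 rose 21.8-fold (4.45 ± 0.89). Pnliprp1 (4.71), Cela1 (4.67), Zg16 (4.32), Try5 (4.25), Ctrc (4.08) and Cela2a (16.0-fold), which encode further enzymes and granule proteins, also rose. PLN spots were saturated on 1 array for Cpb1, Cel, Amy2, Pnliprp1, Cela1 and Zg16 and on 2 arrays for Ctrc, which lowers their ratios.

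Genes of macrophages and monocytes rose in PLN over ILN (list median 0.36, above 0 on 3 of 3 arrays, adjusted p = 5.74e-07; adjusted p = 0.382 with an estimated correlation). Over all genes tested 9 of 23 rose, 1 fell and 13 did not pass, and adjusted over the list alone 14 were higher and 2 lower. Marco, a scavenger receptor of medullary and marginal zone macrophages, rose 3.38-fold (log2 1.76 ± 0.09, SE of the fit, n = 3; adjusted p = 0.000198). Hmox1, which degrades haem, rose 2.30-fold, the iron exporter Slc40a1 2.29-fold and Adgre1, which encodes F4/80, by 1.11 on the log2 scale. Ccr2, a monocyte chemokine receptor, fell by 0.63. Genes of lymphatic endothelium rose (list median 0.58, above 0 on 3 of 3 arrays, adjusted p = 0.00191; adjusted p = 0.382 with an estimated correlation). Of 7 measured, 4 rose over all genes tested and adjusted over the list alone, and 3 did not pass. They were Lyve1, a hyaluronan receptor, at 1.11 ± 0.12 (2.16-fold, adjusted p = 0.00409), the scavenger receptor Stab2 at 0.81 ± 0.08, Reln at 0.60 ± 0.09 and Tbx1 at 0.58. The T cell list had a median of -0.23, below 0 on 3 of 3 arrays, and -0.10 with median centring (adjusted p = 1.63e-06; adjusted p = 0.382 with an estimated correlation). Over all genes tested 4 of 27 fell and 23 did not pass, and adjusted over the list alone 13 were lower and 1 higher. Dapl1 was at -0.62 ± 0.07, Il7r, the receptor of interleukin 7, at -0.50 ± 0.09 and Cd6 at -0.30.

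Lum, which encodes the matrix proteoglycan lumican, rose 6.43-fold in PLN over ILN (log2 2.69 ± 0.13, SE of the fit, n = 3; adjusted p = 0.000198). Of 15 genes of fibroblastic stroma 4 rose, 0 fell and 11 did not pass in limma. The others that rose were Fn1 (1.19 ± 0.12, with 1 of 3 probes of the opposite sign), Grem1 (0.83) and Dcn (0.56). Madcam1 rose 3.23-fold (1.69 ± 0.23, adjusted p = 0.0108) and Nkx2-3 2.10-fold (1.07 ± 0.13, adjusted p = 0.00732). Aldh1a2 rose 2.93-fold (1.55 ± 0.14, adjusted p = 0.00285). Cyp26b1 fell by 1.30 ± 0.08 on the log2 scale (adjusted p = 0.000382). Of 18 genes of the splanchnic and anterior body 3 rose and 15 did not pass in limma (list adjusted p = 0.253). Gata6 (0.50, 1 of 3 probes opposite) and Hoxb2 (0.39) were among those that rose. Hoxc9 was at least 1.52-fold lower in PLN (adjusted p = 0.0469), where it was not well above background. Ccl8, a monocyte chemoattractant, fell by 1.70 ± 0.30 and the calcium-binding S100a6 by 1.01 ± 0.07, and the related chemokine Ccl12 fell too (adjusted p = 0.00305). Of 18 cytotoxic and natural killer cell genes 2 fell and 16 did not pass, and 2 were higher and 4 lower adjusted over the list alone (list adjusted p = 0.112). Receptors of these cells, Klra16 (-1.18) and Klrd1 (-0.72), and the cytotoxic granule gene Nkg7 (-0.46) were lower. So were Cd207 of Langerhans cells (-0.56), the scavenger receptor gene Cd163l1 (-0.94), Pdgfrl (-0.73), Wnt10a (-0.70), the endothelial gene Emcn (-0.42) and the smooth muscle genes Tagln (-0.93) and Mylk (-0.50).

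Further genes that rose in PLN over ILN were the heat shock genes Hspa1a (0.68, 1 of 4 probes opposite) and Dnajb1 (0.30) and the immediate early gene Nr4a1 (0.47). Of 23 immediate early and stress genes 3 rose and 20 did not pass (list adjusted p = 0.252). Adjusted over the list alone, 6 were higher and 3 lower. Pdcd1 and Tnfrsf9 of activated T cells (0.47 and 0.61), Itgax of dendritic cells (0.43), Krt20 (0.35) and Mbp (0.35, 1 of 3 probes opposite) rose as well. White adipose genes had a list median of 0.55 (adjusted p = 0.00332; adjusted p = 0.706 with an estimated correlation). None of the 20 measured passed limma's test, 0 over all genes tested and 0 adjusted over the list alone. Their median was -0.27 on the FVB array, 0.98 on the NOD array and 1.03 on the NOD.B10 array. Car3, a carbonic anhydrase abundant in fat, was at 1.36 ± 0.41 (SE of the fit, n = 3; adjusted p = 0.132). Plasma cell genes had a median of 0.26 (adjusted p = 0.0114; adjusted p = 0.579 with an estimated correlation). Of 14 measured, 0 passed over all genes tested, and 1 was higher and 1 lower adjusted over the list alone. Jchain, which joins secreted antibodies, was at 1.04 ± 0.40 (adjusted p = 0.203), with 2.66 on the FVB array and 0.22 on each of the others. The plasma cell median was 0.62 on the FVB array against 0.05 and 0.09 on the NOD and NOD.B10 arrays. Glycam1 was at -0.15 (adjusted p = 0.470), with the sign turned by median centring, and Ins2 at 0.95 ± 0.57 (adjusted p = 0.363). Ins2 was at 2.62 on the FVB array, -0.01 on the NOD array and 0.25 on the NOD.B10 array, and was well above background in 1 of these 3 PLN samples.

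The count of 589 was 32 without the NOD.B10 array of the ILN, 370 without the FVB array of the ILN, 269 without the FVB array of the MLN and 0 with median centring. The adipose call was lost without NOD (adjusted p = 0.291) or NOD.B10 (0.112) and the plasma cell call without FVB (0.590). Within the later scanner 339 genes and with scanner as a block 495 genes were called. There 40 and 43 of the 51 called genes named under the rule kept their call. The list medians there were 3.51 and 3.53 for acinar genes and unmoved for the adipose (0.55), lymphatic (0.58), plasma cell (0.26), T cell (-0.23) and macrophage lists (0.36). All ILN arrays lay on the later scanner, so neither setting could move the PLN over ILN ratio of a gene, only its spread. Aldh1a2, Cd207, Cyp26b1, Fn1, Klrd1, Lum, Marco and S100a6 were among those that kept their call without each array in turn. Of the 51 named genes 9 kept it without the NOD.B10 array of the ILN, 31 without NOD, 30 without FVB and 29 without the FVB array of the MLN.

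**Figure D2:**
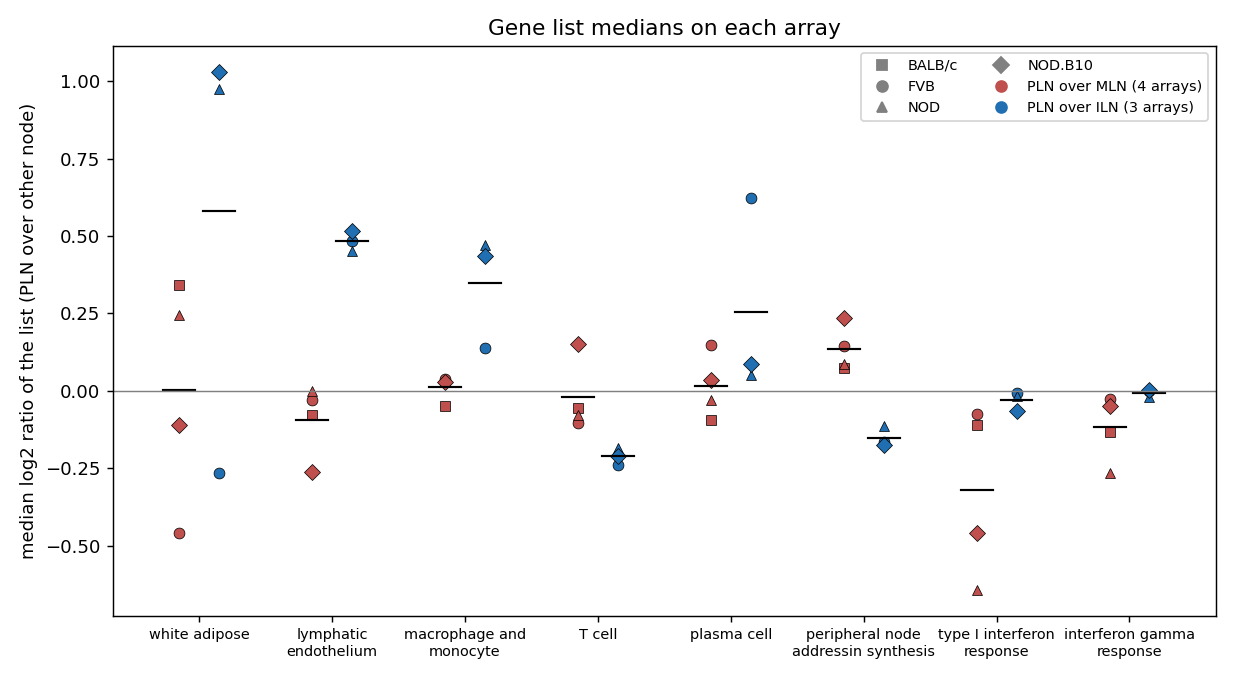
Median log2 ratio of PLN over the other node (vertical axis) of 8 gene lists on each array, coloured by the other node and shaped by strain, with bars at the mean over the arrays of a comparison. Lymphatic medians lie at 0.45 to 0.52 and T cell medians at -0.24 to -0.19 against ILN, and the type I interferon and interferon gamma medians against MLN, below 0 here, turn above 0 with median centring of each array in place of loess.

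ILN and MLN were compared through the PLN on each array, so that a dye effect of a probe cancels, but a difference between the PLN samples does not. For all 25 called genes named under the rule the levels of the ILN and MLN channels differed with the same sign. These levels come from the same spots as the tested ratios, so their sign is no independent check. limma called 76 genes, 13 higher and 63 lower in ILN, with 4 and 22 changed at least 2-fold. Lum fell by 2.32 ± 0.17 on the log2 scale (SE, 7 arrays; adjusted p = 0.00261), Aldh1a2 by 2.22 ± 0.19 (adjusted p = 0.00357) and Marco by 2.07 ± 0.12 (adjusted p = 0.00109). For each of them the ratios of the 4 MLN and the 3 ILN arrays did not overlap, which the rule for the largest genes required. Cyp26b1 rose 2.50-fold (1.32 ± 0.10, adjusted p = 0.00295), opposite to Aldh1a2. The calcium-binding S100a4 and S100a6 rose 2.48-fold and 2.32-fold (1.31 ± 0.12 and 1.21 ± 0.10). Fndc5 (-1.41 ± 0.10), Dnah2 (-1.57), Apol7c (-1.54), Nkx2-3 (-1.30), Asb2 (-1.29), the interferon-induced GTPase Gbp2b (-1.27), Dcn (-1.07) and Vpreb3 (-0.44, turned by median centring) were lower. Madcam1 was at -1.48 ± 0.30 and did not pass (adjusted p = 0.131).

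Macrophage genes had a median of -0.40 in ILN over MLN on the loess scale and of 0.30 with median centring (adjusted p = 7.23e-08; adjusted p = 0.382 with an estimated correlation). Over all genes tested 3 of 23 fell and 20 did not pass, and adjusted over the list alone 14 were lower and 3 higher. The ones that fell were Marco, Adgre1 (-1.20 ± 0.15) and the mannose receptor Mrc1 (-0.53). The lymphatic list had a median of -0.52, and -0.05 with median centring (adjusted p = 4.22e-07; adjusted p = 0.382 with an estimated correlation). Of the 7 measured, Lyve1 fell by 1.35 ± 0.15 (adjusted p = 0.0142), 6 did not pass over all genes tested and 4 were lower adjusted over the list alone. The addressin list had a median of 0.23, and 0.42 with median centring (adjusted p = 0.0004; adjusted p = 0.382 with an estimated correlation). The enzyme gene Fut7 rose by 0.84 ± 0.11 (adjusted p = 0.0286), 6 of 7 did not pass, and 3 were higher adjusted over the list alone, with Glycam1 at 0.77. The T cell list had a median of 0.20, and 0.98 with median centring (adjusted p = 5.18e-06; adjusted p = 0.382 with an estimated correlation). In limma 0 of 27 passed over all genes tested, and 5 were higher adjusted over the list alone, among them Dapl1 (0.41) and Il7r (0.39). The smooth muscle list had a median of 0.14, and 0.83 with median centring (adjusted p = 7.97e-05; adjusted p = 0.382 with an estimated correlation). Of 11 measured, 0 passed over all genes tested and 3 were higher adjusted over the list alone, Tagln (0.85), Cnn1 (0.65) and Mylk (0.46). With offset 0, Agilent's LogRatio and the deposited values the lymphatic median was -0.85, -0.89 and -0.84, the addressin median 0.54, 0.82 and 0.82 and the smooth muscle median 0.20, 0.40 and 0.40. The chemokine genes Ccl5 (0.71) and Ccl12 (0.82), the B cell survival factor gene Tnfsf13b (0.61), Wnt10a (0.90), Lgals1 (0.75), Vim (0.63) and Emcn (0.57) rose.

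White adipose genes had a median of -0.59 in ILN over MLN, and 0.04 with median centring (adjusted p = 0.000787; adjusted p = 0.692 with an estimated correlation), with Car3 at -1.53. Type I interferon genes had a median of -0.31, which was 0.22 with median centring (adjusted p = 1.12e-07; adjusted p = 0.522 with an estimated correlation). Isg15 was at -0.80, with a log2 level in MLN of 9.86 in NOD and 7.81 to 8.84 in the other strains. The germinal centre median was -0.17, and 0.15 with median centring (adjusted p = 0.00632; adjusted p = 0.471 with an estimated correlation). The plasma cell median was -0.22, and 0.38 with median centring (adjusted p = 0.0255; adjusted p = 0.630 with an estimated correlation), with Jchain at -1.01 (-0.19 without the FVB array of the ILN). The interferon gamma median was -0.08, and 0.74 with median centring (adjusted p = 0.032; adjusted p = 0.552 with an estimated correlation), with the chemokine gene Cxcl10 at -0.90. In these 5 lists limma called 0 genes over all genes tested, and adjusted over the list alone 2 interferon gamma genes were lower. Erythroid genes had a median of 1.04, and 2 of 6 were higher adjusted over the list alone (list adjusted p = 7.97e-05; adjusted p = 0.458 with an estimated correlation), with Hba-a1 at 2.20. The Hba-a1 levels of ILN and MLN themselves differed by 0.06, so that ratio rests on PLN levels that differed between arrays. Mammary and skin epithelial genes had a median of 0.13 (0.38 with offset 0, 0.57 with Agilent's LogRatio and 0.67 in the deposited values), and 0 of 15 passed adjusted over the list alone (list adjusted p = 0.00421; adjusted p = 0.458 with an estimated correlation). The milk protein gene Csn3 was at 0.76, with PLN ratios of -1.83 on the FVB array of the ILN and -0.36 and -0.09 on those of NOD and NOD.B10. With Agilent's LogRatio and in the deposited values the medians were -0.61 and -0.61 for type I interferon, -0.28 and -0.30 for germinal centre, -0.34 and -0.34 for plasma cell, -0.14 and -0.12 for interferon gamma and 1.69 and 1.69 for erythroid genes. Type I interferon genes were at -0.49 with offset 0, and germinal centre genes at -0.09 with no background correction. With median centring the median of all genes was 0.13 in ILN over MLN. Relative to it the mammary list lay at -0.04, the adipose list at -0.09, the lymphatic list at -0.18, the type I interferon list at 0.08, the macrophage list at 0.16, and the germinal centre, plasma cell and interferon gamma lists at 0.02, 0.25 and 0.61.

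With strain as a block, 26 genes were called between ILN and MLN, 23 of them among the 76. Within the later scanner 7 genes and with scanner as a block 18 were called. Among 25 called genes named under the rule 14 kept their call with strain as a block, while Lyve1 (adjusted p = 0.128) and Nkx2-3 (0.109) were among those that did not. Within the later scanner 5 kept it (Fndc5, Lum, Lyve1, Marco and S100a6), and 8 with scanner as a block. The count was 32 without the BALB/c array, 30, 33 and 32 without the FVB, NOD and NOD.B10 arrays of the MLN, 17 and 15 without the NOD and NOD.B10 arrays of the ILN, and 0 with median centring. Within the later scanner and with it as a block the medians were equal, because both settings take each ratio from the same arrays. They were -0.99 for adipose, 0.11 for mammary, 0.26 for smooth muscle, -0.52 for lymphatic, 0.18 for addressin, -0.24 for germinal centre and 0.23 for T cell genes. For macrophage genes they were -0.42, for type I interferon genes -0.27 and for erythroid genes 0.71, and all of these lists passed there. Plasma cell (-0.17) and interferon gamma genes (-0.04) did not pass there.

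Calls of lists between ILN and MLN were also lost without single arrays. Without the FVB array of the ILN they were lost for mammary (adjusted p = 0.0798), germinal centre (0.0709), plasma cell (0.924) and interferon gamma genes (0.105). Without the NOD array of the ILN they were lost for adipose (0.235) and interferon gamma genes (0.0705), and without that of NOD.B10 for adipose genes (0.0942). Without the BALB/c array the plasma cell call was lost (0.0820), and without the NOD array of the MLN that of interferon gamma genes (0.230). Without the NOD.B10 array of the MLN, adipose (0.0882), germinal centre (0.107), plasma cell (0.0971) and interferon gamma genes (0.0982) lost theirs.

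**Figure D3:**
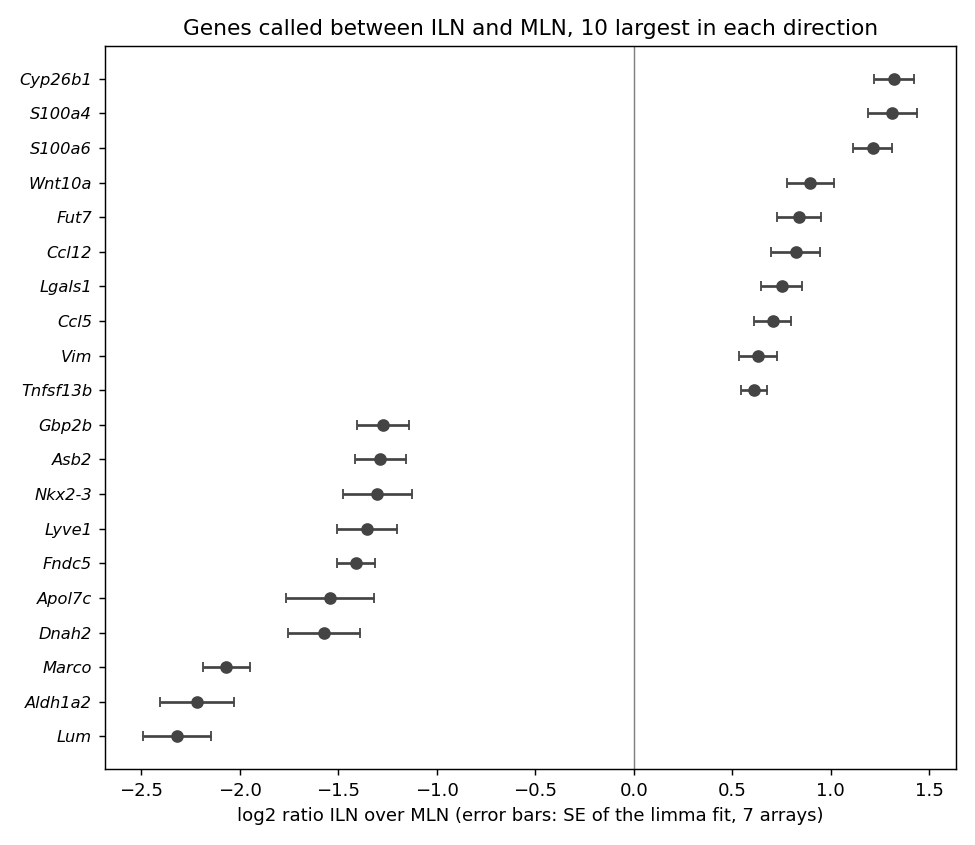
Log2 ratio of ILN over MLN (horizontal axis) of the 10 largest called genes in each direction, with bars for the SE of the limma fit to 7 arrays. Lum, Aldh1a2 and Marco lie at -2.32, -2.22 and -2.07 and Cyp26b1 at 1.32.

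The genes that set the PLN apart from both other nodes were counted as those called with the same sign against MLN and ILN. limma called 0 such genes, as 0 were called against MLN, where 4622 genes had an unadjusted p under 0.05, and independent lists would share 0. Over genes the log2 ratios of both comparisons correlated at r = 0.704, against 0.435 in 20 simulated sets of unchanged arrays that shared their PLN. Their covariance was 0.0285 against 0.0033, a difference of 0.0252. Where no strain gave both ratios, the covariance was 0.0127 to 0.0248 and 0 genes were shared. In these parted sets limma called 2, 0 and 0 genes against MLN and 964, 0 and 0 against ILN, so hardly any could be shared. A dye effect of a probe enters both ratios, as PLN carried the same dye on every array. Neither the simulation nor the parting of strains can tell it from a difference of the PLN. Without the BALB/c array 39 genes were called against both nodes, 24 of them acinar genes, and without the FVB array of the ILN 4. Within the later scanner 17 were called, 9 of them acinar genes.

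NOD and NOD.B10 mice were compared without a test, as each gave 1 pool per node. In 3 genes the PLN ratio was higher in NOD by at least 1 on the log2 scale against both MLN and ILN, and 0 were lower. Counted in either direction there were 10 between FVB and NOD and 12 between FVB and NOD.B10. Genes that differed by as much in opposite directions against MLN and ILN numbered 1 between NOD and NOD.B10. There were 41 of these between FVB and NOD and 18 between FVB and NOD.B10. The 3 genes higher in NOD were Lars2, Pigt and a probe without a gene name, whose spots were saturated in both channels on 3 or 4 arrays, and 0 remained without such spots. H2-Ea is an MHC class II gene expressed in haplotype d and silent in haplotypes b and g7. It had a log2 level of 10.2 in PLN and 10.5 in MLN of BALB/c. It was at 7.42 to 7.75 in the FVB samples and was well above background in each of them. In the NOD and NOD.B10 samples it was at 6.01 to 6.79 and well above background in 1 sample, the ILN of NOD.B10. Its PLN ratios were -0.16 against MLN (adjusted p = 0.255), turned by median centring and in the deposited values, and -0.26 against ILN (adjusted p = 0.0824). Deaf1, a transcription factor that drives tissue antigens in lymph nodes, was at 1.26 ± 1.40 (SD, n = 4; adjusted p = 0.254) against MLN and 0.64 against ILN (adjusted p = 0.466). It was at 3.31 on the NOD array of the MLN and 0.15 to 1.05 on the others. Aire, which drives tissue antigens in the thymus, was at 0.10 against MLN (adjusted p = 0.372) and 0.14 against ILN (adjusted p = 0.243). In ILN over MLN, Deaf1 was at 0.62 (adjusted p = 0.935), Aire at -0.04 (adjusted p = 0.977, turned by median centring), H2-Ea at 0.09 (adjusted p = 0.916) and Ins2 at 1.05 (adjusted p = 0.888). The ILN and MLN levels themselves differed with the opposite sign for Deaf1 (-0.12), H2-Ea (-0.70) and Ins2 (-0.64), so these 3 ratios rest on PLN levels that differed between arrays.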

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

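The tests of a dye effect fixed per probe, of genes of many tissues and of a fixed proportion of acinar cells and islets, the spread condition for the other probes and the condition that each member lie under 1, the splits that part strain pairs and the fit within the later scanner were chosen after the results were seen. In the outlier check of the 4 MLN arrays 5 of 115 results stood out, where 5.75 are expected, since chance marks about 1 in 20 groups. The median of macrophage genes was -0.0504 on the BALB/c array and 0.03 to 0.04 on the others. Hmox1 was at 0.2034 on the BALB/c array and 0.59 to 0.61 on the others. On the NOD.B10 array Il1rl1 was at 1.4038 (0.13 to 0.35 on the others), Krt20 at 0.4302 (0.07 to 0.13) and Fut7 at 0.6671 (0.39 to 0.43).

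Among 116 results, 12 pairs of strains had all PLN ratios of one strain above 0 and all of the other below 0, and these differences were not tested. The mean ratio of white adipose genes was 0.61 in NOD and -0.36 in FVB, a difference of 0.9739, and that of Car3 1.11 and -0.50, a difference of 1.6099. Cell cycle genes were higher in FVB than in NOD by 0.3637 and than in NOD.B10 by 0.3609. Islet genes were higher in FVB than in NOD.B10 by 0.1132, and smooth muscle genes in NOD.B10 than in NOD by 0.1317. Mesothelial genes were higher in FVB and NOD than in NOD.B10 by 0.1015 and 0.1927. B cell genes were higher in NOD.B10 than in FVB by 0.1431, and dendritic cell genes in NOD than in FVB by 0.075. Immediate early genes were higher in FVB and NOD.B10 than in NOD by 0.1499 and 0.0508.

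Acinar genes were higher in PLN on 6 of the 7 arrays, with list medians of 2.98 to 4.80. On the BALB/c array their median log2 level was 13.5 in PLN and 13.1 in MLN, against 9.05 to 11.3 in the other MLN and ILN samples. The highest of 8 medians of 4 lists of other tissues was 0.0466 and none of their 61 members reached 1 (highest 0.39). For these lists that argues against a joint rise in PLN over the other nodes at the size of the acinar ratio. Expression alike in all nodes would cancel in these ratios and was not tested. The intestinal and the mammary and skin lists are also of tissues that the MLN and ILN drain, which can lower their ratios. Pancreatic tissue with acinar cells and islets in a fixed proportion is argued against, as 3 arrays had an acinar median over 3 and an Ins2 ratio under 0.5. A dye effect fixed per probe as the whole cause is argued against, as all arrays have the same dyes, yet 33 of 33 acinar genes ranged over the 6 arrays more widely than 95% of all genes (median range 2.21 against a 95th percentile of 0.88), and so did the 15 without saturated PLN spots. A contribution of such an effect stays open, since the 4 other probes of acinar genes had a median of 2.4319 with an SD of 2.02. Acinar tissue in the PLN RNA, such as pancreas left at the node, also stays open, because 5 acinar genes that are not secreted enzymes had a median of 0.4902 (Rbpjl 1.18, Cckar 1.07, Gatm 0.49, Slc39a5 0.15 and Nr5a2 -0.03), and expression by cells of the node was not tested.

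The Ins2 ratio of NOD was 2.90 against MLN and -0.01 against ILN. Ins2 RNA in the ILN is argued against, as the ILN level of NOD was lower than the mean of the other ILN samples (difference -0.2657). A single PLN RNA on both NOD arrays is argued against too, as the PLN levels of Ins2 differed by 4.0014, more than in 99.98% of genes. The PLN levels of acinar genes differed by a median of 2.26. These levels were compared across the 2 scanners, and the 95th percentile of the absolute difference over all genes was 0.83. Whether the PLN RNAs of the NOD arrays were separate pools or came from nodes taken with different amounts of pancreas was not tested.

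limma called 0 genes in PLN over MLN, with 4622 at an unadjusted p under 0.05, beside 589 in PLN over ILN. Without the BALB/c array it called 46, and within the later scanner 19, which lie between the bounds set for either cause, so neither array nor scanner can be excluded or singled out. As the only array of its strain, the BALB/c array and its strain cannot be told apart. The NOD array of the MLN, from the same earlier scanner, had an acinar median of 4.80 against 0.12 on the BALB/c array, and without that NOD array 0 genes were called. Of 35 splits of the arrays into 4 and 3, only the real one reached the 76 genes called between ILN and MLN. The highest other count was 6. This share (count 1) lies under 0.05, and it argues against chance only if the 2 arrays of a strain are taken as independent. It does not exclude chance. Among the 8 splits that part the arrays of each of the 3 strains (real 76, highest other 0), the splits are too few for a share under 0.05, and with strain as a block 26 genes were called. For PLN over MLN (real 0, highest other 0, 8 of 8 sets of signs) and PLN over ILN (real 589, highest other 0, 1 of 4 sets) the sets of signs are too few for a share under 0.05.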

How the results depend on the processing

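The scanner settings and the setting without saturated spots were chosen after the data were seen. Counts follow the order PLN over MLN, PLN over ILN, ILN over MLN and shared PLN genes (0, 589, 76 and 0 as reported, limma; 4622 genes in PLN over MLN had an unadjusted p under 0.05), and the cause was not tested unless stated. Without background correction they were 37, 531, 79 and 11, with offset 0 they were 0, 49, 3 and 0, with median centring 0, 0, 0 and 0, with Agilent's LogRatio 0, 66, 12 and 0, and with the deposited values 0, 32, 0 and 0. The strict filter, which tests fewer genes, gave 10, 836, 129 and 5, trend and robust moderation 0, 74, 68 and 0, array weights 189, 1560, 178 and 66, and NOD averaged with NOD.B10 (fewer arrays) 0, 97, 14 and 0. The arrays of PLN over ILN alone gave 205, and the 2-fold threshold 54 in PLN over ILN and 26 in ILN over MLN. The replicate block of strain as a fixed term gave 26 and as a random term 120 in ILN over MLN, 576 in PLN over ILN. The later scanner alone gave 19, 339, 7 and 17, and scanner as a block 0, 495, 18 and 0. Without each array in turn the counts were 0 to 46, 32 to 738, 15 to 87 and 0 to 39, and the lone arrays left are assumed to vary like the others. Calls with offset 0 were 87.8% higher in PLN over ILN (76.4% as reported) and 0% higher in ILN over MLN (17.1%). The other settings stayed within 1.5 times, and Aquantile changed no count. Slide could not be a block.

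Of 108 gene list tests 27 passed, 0 with an estimated correlation, 25 to 32 without each array in turn, 23 within the later scanner and 21 with scanner as a block. Of the 27 themselves 22 to 26 passed without each array in turn, 20 within the later scanner and 19 with scanner as a block. Without a replicate block 12 lists passed in ILN over MLN, with it 15, the 12 among them. Of 114 results for named genes 76 passed, 9 of them in every setting run for named genes and 16 without each array in turn, and no called gene changed sign there. Those settings do not include median centring, which turned 1 called gene (Vpreb3) and 6 results that were not called, or the deposited values, which turned 0 and 2. Reversed in the settings run for named genes were 2 results that were not called. Cyp26b1 PLN vs MLN was at -0.0732 with Agilent's LogRatio and -0.0353 to 0.0769 without each array in turn (-0.0196 without BALB/c, lowest without NOD.B10). Deaf1 ILN vs MLN was at -0.0667 to 0.986 without each array, lowest without the NOD array of the MLN. With Agilent's LogRatio 59 named results fell below the threshold, with no background correction 5 and with no filter 7. Strain as a block ended the call of 11 of 25 named genes in ILN over MLN. For NOD against NOD.B10, 3 genes became 710 with Agilent's LogRatio, 0 at a difference of 1.5 and 0 without spots saturated in both channels. With Agilent's LogRatio the same rule gave 870 genes between FVB and NOD and 590 between FVB and NOD.B10. The 710 were dim, with a median log2 signal of 6.48 against 6.70 for all genes. Their highest was 7.81, below the upper quartile of all genes (7.84). Of all probes 46.0% to 59.1% were well above background in the PLN channel.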

Other observations

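The islet hormones and the genes named without the BALB/c array were chosen after their values were seen. Of the 36 gene lists 19 passed in no comparison, with medians of -0.11 to 0.17 and a lowest adjusted p of 0.0518. These were the lists of B cells, dendritic cells, regulatory and activated T cells, cytotoxic and NK cells, type 17 and innate lymphoid cells, mast cells, blood endothelium, fibroblastic stroma, mesothelium, duct and intestinal epithelium, brown adipose tissue, skeletal muscle, neural and glial cells, anterior Hox and splanchnic genes, retinoic acid and gut homing, the cell cycle, immediate early and stress genes and the circadian clock. Fibroblastic stroma had medians of 0.08, 0.07 and -0.03 in PLN over MLN, PLN over ILN and ILN over MLN, and the genes of retinoic acid and gut homing -0.05, -0.05 and 0.02, although Lum, Aldh1a2 and Cyp26b1 of these lists were called.

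Of the islet hormone genes besides Ins2, Ins1 and Gcg differed most between arrays. Iapp was at 0.56 on the BALB/c array and -0.01 and -0.02 on the NOD arrays, Sst at 0.44 and 0.11 on the NOD arrays of the MLN and the ILN, and Ppy was not well above background in PLN on either NOD array. Ins1 was at 1.28 on the BALB/c array, 0.95 and 1.11 on the FVB arrays, 1.46 on the NOD array of the MLN, -0.01 on the NOD array of the ILN and 0.03 and -0.04 on the NOD.B10 arrays. Gcg, which encodes glucagon, was at 0.60 on the BALB/c array, above 1 on both FVB arrays (1.02 on that of the MLN), 0.81 on the NOD array of the MLN, -0.03 on that of the ILN and -0.23 and -0.08 on the NOD.B10 arrays. On the same NOD array of the ILN the acinar median was 3.09. Without the BALB/c array Krt18 (2.35 ± 0.23), a keratin of simple epithelia, Pnlip (5.36 ± 0.34) and Reg1 (5.60 ± 0.60) were among the 46 genes called in PLN over MLN (SE, 6 arrays).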
